A study of Mus musculus with 6 samples.

How the data were processed

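Total RNA of whole back skin was measured in 6 samples, 3 per group, on single-colour (Cy3) Agilent mouse arrays. Per the labels, RNA was extracted with TRIzol, and labelled cRNA was made by linear amplification. The authors deposited 1 scanner file per sample and 1 value table. The deposited scanner values are spot intensity on a linear scale: a processed signal, after background subtraction and detrending per the file headers, and the mean and background signals before subtraction. Per the file headers, Agilent Feature Extraction 10.7.3.1 made the scanner files, while the submitters' processing notes name version 9.1. The deposited value table is on a log2 scale: each column rose by 0.973 to 1.01 per log2 unit of processed signal of the array it matched. Its column medians all lay at 7.05, and the normalization between arrays is not stated.

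Samples took their groups from the titles, and each scanner file was assigned to the sample it was filed under. Control spots were left out, as were 322 spots marked by the extraction software as non-uniform or population outliers on any array, and the log2 signals of a probe's spots were averaged, which left 41115 of 41174 probes. Values were the log2 processed signal minus each array's 75th percentile. Probes were tested when well above background on at least 3 of the 6 arrays, whatever their group (27415 probes). Each gene was represented by its tested probe of highest mean, which gave 17778 genes, 14329 of them with a gene symbol and 6595 with several tested probes. Among the named genes with several tested probes, all probes had the same sign, and the other probe of Serpinb3a differed by -6.46. Probes were named through RefSeq accessions (27668) or as the synonym of a single gene (471), and otherwise kept the file's name; Il36a appears in the file as Il1f6. Positions are the mm9 positions of the array files.

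Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates, two-sided) with Benjamini-Hochberg adjustment at 0.05. The 23 gene lists, 12 of pathways and structures and 11 of cell types, were fixed before the data were examined, as were the rule for named genes and all alternatives but 1. Lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated per list. These tests called 17 and 0 lists. Lists share members, and each measured gene of the imiquimod response list is also in another list, so list results are not independent. The rule named the 5 secreted frizzled-related protein genes; the 3 highest and 3 lowest fitted differences, dim groups included, among symbols that passed without overlap between groups; the 3 members of smallest p of the imiquimod response list and the 2 of each other pathway list; and the 1 of each cell type list. Not every gene that the rule named is reported. Members outside it that are named where 5 or fewer of a list rose or fell were chosen after their values were seen. Where a gene's probe was well above background on no array of a group, its fold is a bound: the mean log2 signal of the brighter group minus that of the dimmer group, after raising each dim value to the lowest signal of any probe well above background on that array. That lowest signal is a lenient floor, so a fold given as at least a value holds at this floor only. Such a fold is for group means, and the adjusted p beside it is that of the fitted difference.

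The steps were tested on simulated data for 3 against 3 arrays over 17778 genes, drawn from the real gene means and residual spreads, with 200 genes changed. The fit recovered 52% of the 50 genes changed by a log2 value of 1, 90% at 2, 94% at 3 and 96% at 4, and called 13 of 17538 unchanged genes. Camera called 2 of 2 lists of 20 genes shifted by 1 and 0 of 20 unshifted lists. Simulated genes varied independently of each other, with the same spread in both groups. In the real arrays 23.6% of genes were called and the groups differed in spread, so these rates may not carry over.

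Scan date followed the slide, and slide was tested as a block and within slide 1. Slide 2 held 1 group only, so both give the same estimates with different residual degrees of freedom. Replicate numbers did not pair the samples: deviations of same-numbered arrays from their group means correlated at -0.0872, 0.0675 and 0.0854 across genes, which are not independent replicates. Pearson correlations of arrays across 24253 probes were 0.960 to 0.983 within the arrays filed under imiquimod, 0.992 within those filed under vehicle and 0.942 to 0.954 between groups. The extraction software set the quality status of arrays 2 and 3 filed under imiquimod to evaluate, for mean net signals of the negative controls of 40.9 and 45.2, against 31.7 to 37.6 on the others. The alternatives were quantile normalization, normexp background correction with an offset of 50, no filter on dim probes, a filter on all 6 arrays, the mean of a gene's probes, a variance trend with robust estimation, slide as a block, slide 1 alone, the replicate number as a block, each array left out in turn, the value table, camera with an estimated correlation, other fold thresholds and, added later, leaving out both arrays of status evaluate, which leaves 1 array against 3. Apart from the alternative with an estimated correlation, lists were tested at the preset one.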

Results

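Gene expression in whole back skin of female C57BL/6J mice, an inbred laboratory strain, was measured after 7 days of a daily cream on the shaved back. The cream held 5% imiquimod, an agonist of the receptor Tlr7 that provokes a psoriasis-like inflammation of mouse skin, or was a vehicle cream, at 62.5 mg per day. The mice were 6 to 8 weeks old. Each group held 3 samples, each on 1 single-colour Agilent mouse array of 45018 spots, of which 43379 were not controls. The labels number the samples of a group without stating that each came from a separate animal, so the p-values measure the spread between these samples, which may be partly technical. Between 61.2% and 67.4% of the probes were well above background on an array, and the 75th percentile of the processed signal lay between 861 and 1106. The number of arrays limits the precision of the values.

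The records did not give the treatment of each array in 1 way. Each scanner file carried in its name the treatment opposite to that of the sample it was filed under, in 6 of 6 files. In 6 of 6 columns, the deposited value table matched the scanner file of the same-numbered sample of the other group. The Spearman correlation with that file was at least 0.9999997 over 24253 probes, against 0.943 to 0.953 with the sample's own file. Groups are given here as the scanner files were filed, and each difference is the log2 signal of the arrays filed under imiquimod minus that of the arrays filed under vehicle. Read by sample title, the value table gave the opposite sign for every list median and every gene named with a difference. By the array headers, slide 1 held the 3 arrays filed under imiquimod and array 1 filed under vehicle, and slide 2 held arrays 2 and 3 filed under vehicle.

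A list of genes known to rise in imiquimod-treated skin was examined first, to ask in which arrays that response lay. All 9 measured genes of the list were lower in the arrays filed under imiquimod, with a median log2 difference of -5.26. In each of the 9 genes, every array filed under vehicle lay above every array filed under imiquimod. Krt6b, a keratin of wounded and hyperproliferative epidermis, differed by -5.41 (SE 0.33, adjusted p = 0.00143). Lcn2, an iron-binding antimicrobial protein, differed by -4.46 (SE 0.34, adjusted p = 0.00178), and Il36a, an epidermal cytokine of the interleukin-1 family, by -4.03 (SE 0.38, adjusted p = 0.00266). Read from the value table, these genes differed by 5.21, 4.43 and 3.97, and the list's median was 5.21. Il17a, Il17f, Il22 and Il23a were too dim to test: they were well above background on 0 arrays filed under imiquimod, and on 2, 1, 1 and 1 arrays filed under vehicle. Adjusted over the list alone, 9 genes were lower. The camera test of the list against all other genes gave an adjusted p of 6.65e-07, and the call was lost, at adjusted p = 0.372 with an estimated correlation. The median was -5.82 within slide 1, and the estimate with slide as a block is the same because slide 2 held 1 group only; 5 lower genes passed with that block.

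**Figure D1:**
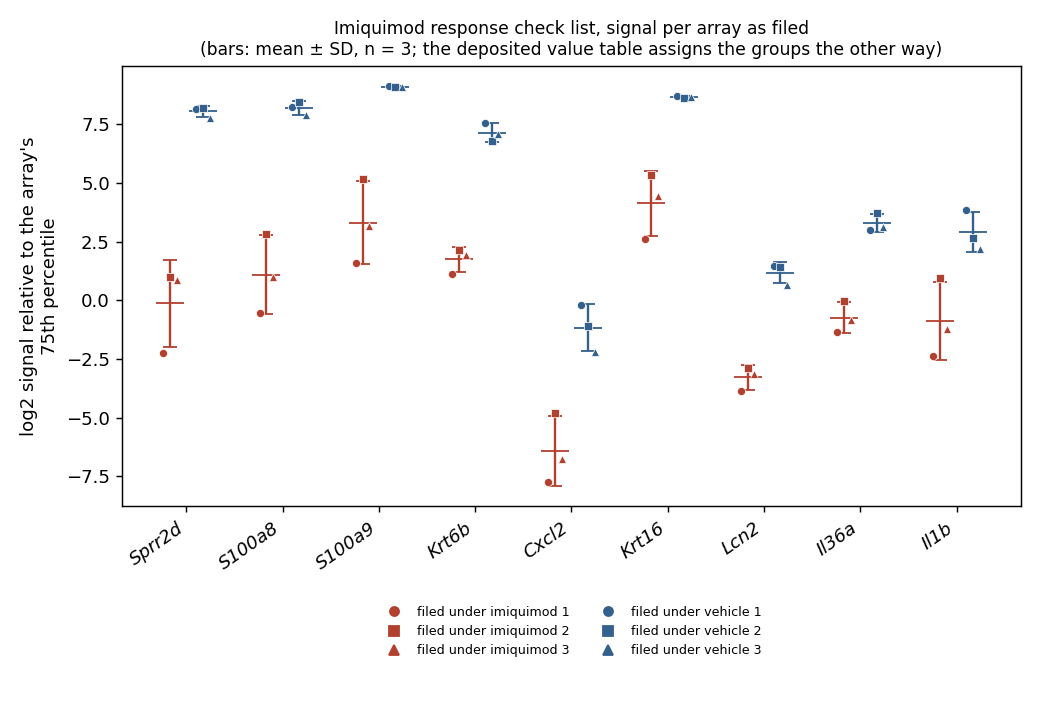
Log2 signal relative to each array's 75th percentile (vertical axis) of the 9 measured genes of the imiquimod response list (horizontal axis), with 1 point per array, coloured by the group its scanner file was filed under, and bars for the mean ± SD of 3 arrays. In each gene the 3 arrays filed under vehicle lie above the 3 filed under imiquimod, and the value table assigns the groups the other way.

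Between the groups, 4196 of 17778 genes (23.6%) changed at an adjusted p under 0.05 in limma. Of these, 1866 were higher and 2330 lower in the arrays filed under imiquimod, and 2122 differed by at least 2-fold. Among the lowest differences of named genes were those of Saa3, an acute-phase protein, at -8.31 (SE 0.69, adjusted p = 0.00207), and of Sprr2d and Sprr2f, small proline-rich proteins of the cornified envelope, at -8.18 (SE 0.89, adjusted p = 0.00370) and -9.05 (SE 1.52, adjusted p = 0.0121). Sprr2f was well above background on 2 of 3 arrays filed under imiquimod, so the size of its difference rests partly on background. Genes of the hair follicle were among the highest. Krt71, a keratin of its inner root sheath, differed by 12.01 (SE 0.82, adjusted p = 0.00162), with 2 of 3 arrays filed under vehicle well above background. Krt25, another such keratin, and Krtap22-2, a keratin-associated protein of hair, were well above background on 0 arrays filed under vehicle. In the mean of the arrays filed under imiquimod they were at least 2363-fold (adjusted p = 0.00203) and at least 1024-fold (adjusted p = 0.00871) higher. Array 3 filed under imiquimod lay below arrays 1 and 2, at 3.77 against 6.56 and 7.48 for Krt25. For Krtap22-2 it lay at 0.54 against 5.65 and 8.00, so these bounds need not hold for each array. The place of both genes among the highest is not established, because bounds do not rank them against the other hair genes. The value-table differences were 8.87 for Sprr2f, 7.96 for Sprr2d, 8.20 for Saa3 and -11.97 for Krt71, and Krt25 and Krtap22-2 were lower in its imiquimod columns. Its counts were 2164 higher and 1806 lower in the imiquimod columns, and of 3701 genes called in both sources, 0 had the same sign.

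With slide as a block, 518 genes were higher, 541 lower and 994 differed by at least 2-fold, and Sprr2f (-8.71, adjusted p = 0.104) and Krtap22-2 (adjusted p = 0.0840) did not pass. Within slide 1, where 3 arrays met 1, 1 gene was higher and 7 lower. Without array 1 filed under imiquimod, 745 genes were higher, 944 lower and 1307 at least 2-fold different. Without array 1, 2 or 3 filed under vehicle, 768, 827 or 854 were higher, 1014, 995 or 1031 lower, and 1356, 1433 or 1428 at least 2-fold different. Without arrays 2 and 3 filed under imiquimod, whose quality status the extraction software had set to evaluate, 1344 were higher and 1617 lower. That alternative was chosen after seeing the data and leaves 1 array filed under imiquimod, so all the spread comes from those filed under vehicle and its p-values are not given for genes.

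The series title concerns the silencing of SFRP4, a member of the secreted frizzled-related proteins, which bind Wnt ligands outside the cell. Sfrp4 was higher in the arrays filed under imiquimod, by 2.20 (SE 0.53, adjusted p = 0.0336), with a mean log2 signal of 1.44 ± 0.87 against -0.76 ± 0.68 (SD, n = 3). Sfrp1 was higher by 1.91 (SE 0.23, adjusted p = 0.00494), at 2.98 ± 0.44 against 1.07 ± 0.11 (SD, n = 3). Sfrp2 was lower, with a difference of -2.47 (SE 0.37, adjusted p = 0.00851), at -0.30 ± 0.66 against 2.17 ± 0.36 (SD, n = 3). Frzb differed by 0.38 (SE 0.36, adjusted p = 0.481) and Sfrp5 by 0.27 (SE 0.23, adjusted p = 0.432), and neither passed; Sfrp5 was well above background on 1 of 3 arrays filed under vehicle. According to the value table, Sfrp4 differed by -2.20, Sfrp1 by -1.95, Sfrp2 by 2.44, Frzb by -0.25 and Sfrp5 by -0.11. The probes lay in mm9 at chromosome 13 from 19724488 to 19724547 for Sfrp4, chromosome 8 from 24558112 to 24558171 for Sfrp1 and chromosome 3 from 83577864 to 83577923 for Sfrp2, at chromosome 2 from 80252582 to 80252641 for Frzb and at chromosome 19 from 42273211 to 42273270 for Sfrp5; no exon annotation of that build was at hand. The Sfrp4 call was lost with slide as a block (2.37, adjusted p = 0.160), without array 1 filed under imiquimod (adjusted p = 0.0921), without array 1 or 2 filed under vehicle (adjusted p = 0.109 and 0.103) and with no filter on dim probes (adjusted p = 0.0551), and its difference was 1.91 to 2.37 in these. The Sfrp1 call was lost with slide as a block (1.94, adjusted p = 0.0514), and Frzb passed without array 3 filed under vehicle (0.79, adjusted p = 0.0400).

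**Figure D2:**
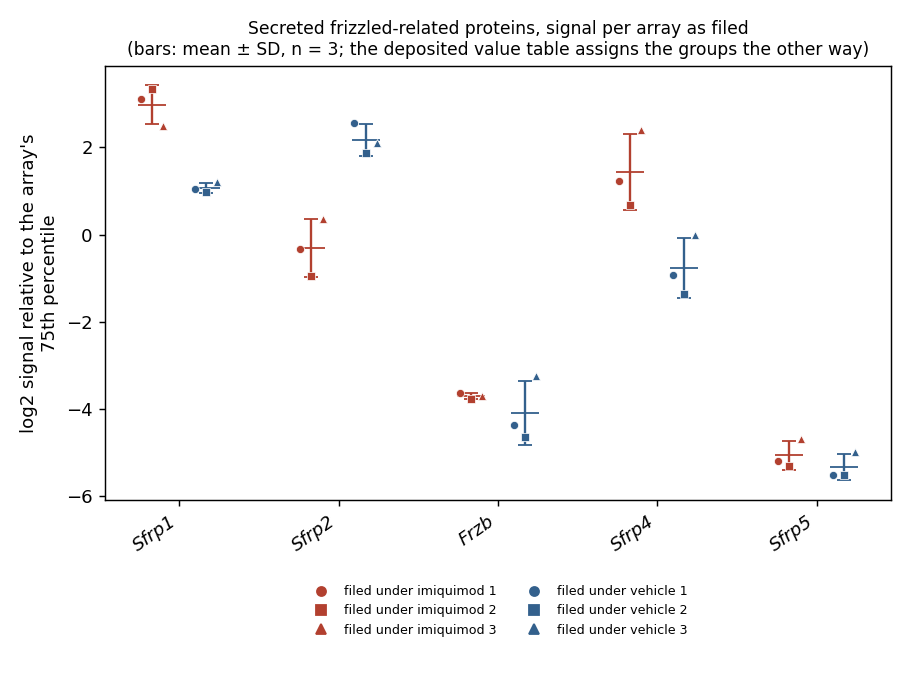
Log2 signal relative to each array's 75th percentile (vertical axis) of the 5 secreted frizzled-related protein genes (horizontal axis), with 1 point per array, coloured by the group its scanner file was filed under, and bars for the mean ± SD of 3 arrays. Sfrp1 and Sfrp4 lie higher and Sfrp2 lower in the arrays filed under imiquimod, and the value table assigns the groups the other way.

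Of 16 measured genes of the Wnt antagonist list, 6 rose in the arrays filed under imiquimod, 2 fell and 8 did not pass. Adjusted over the list alone, 7 rose and 2 fell. Whether each member blocks Wnt signalling in skin was not tested. Notum, an enzyme that inactivates Wnt ligands by removing their lipid, rose by 3.49 (SE 0.49, adjusted p = 0.00753), and Sfrp2 (-2.47, value-table value 2.44) and Dkk3 (-0.88, value-table value 0.84) fell. Notum was well above background on 1 of 3 arrays filed under vehicle, so the size of its rise is measured mostly against background. The median was 0.53 (camera adjusted p = 0.0353), the call was lost, at adjusted p = 0.439 with an estimated correlation, and the median was 0.68 within slide 1. With slide as a block, 1 higher and 1 lower gene passed. The value-table median was -0.52, and Notum differed there by -3.45. The list's call was also lost without array 1 or 2 filed under vehicle (adjusted p = 0.0582 and 0.0540), with the mean of a gene's probes (0.33, adjusted p = 0.0810) and with normexp background correction (0.32, adjusted p = 0.0676), which put Notum at 1.49.

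Of 34 measured Wnt ligands, receptors and target genes, 10 rose in the arrays filed under imiquimod, 2 fell and 22 did not pass; adjusted over the list alone, 11 rose and 2 fell. Wnt3, a ligand, rose by 2.01 (SE 0.20, adjusted p = 0.00312). The ligands Wnt4 (-1.54, value-table value 1.52) and Wnt16 (-1.48, value-table value 1.53) fell, Wnt4 with SE 0.17 and adjusted p = 0.00380. The median was 0.63 (camera adjusted p = 0.00127), the call was lost, at adjusted p = 0.439 with an estimated correlation, and the median was 0.63 within slide 1. The fit with slide as a block left 3 higher and 1 lower gene. The value table gave a median of -0.62 and a difference of -2.02 for Wnt3. Relative to each gene's mean over the 6 arrays, the list stood at 0.43, 0.58 and -0.075 in arrays 1, 2 and 3 filed under imiquimod, and at -0.45, -0.31 and -0.16 in those filed under vehicle, so array 3 filed under imiquimod lay near the latter.

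Among 19 measured DNA methylation and Polycomb genes, 1 rose in the arrays filed under imiquimod, 1 fell and 17 did not pass, with 1 and 1 adjusted over the list alone. Dnmt3l, a cofactor of the de novo DNA methyltransferases, fell, with a difference of -3.26 (SE 0.22, adjusted p = 0.00155). Tet3, which oxidises methylated cytosine, rose by 0.68 (SE 0.14, adjusted p = 0.0199). The list's median was 0.085 and its mean -0.11, which differ in sign, and camera gave an adjusted p of 0.764. The median was 0.058 within slide 1 and -0.036 without array 2 filed under imiquimod, and 1 lower gene passed with slide as a block. By the value table Dnmt3l differed by 3.27 and Tet3 by -0.71, and the median was -0.060. Tet3 did not pass with slide as a block (adjusted p = 0.138), without array 1 filed under imiquimod (adjusted p = 0.0660) or without array 1, 2 or 3 filed under vehicle (adjusted p = 0.0710, 0.0549 and 0.0731), while its difference was 0.61 to 0.74 in these.

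Of 17 measured antimicrobial and IL-36 genes, 15 were lower in the arrays filed under imiquimod, 0 higher and 2 did not pass; adjusted over the list alone, 16 were lower. Lcn2 and Il36a are among the genes that this list shares with the imiquimod response list. Defb14, an epithelial beta-defensin, differed by -3.47 (SE 0.21, adjusted p = 0.00143), beside Lcn2 and Saa3. The median was -3.44 (camera adjusted p = 3.54e-10), the call was lost, at adjusted p = 0.372 with an estimated correlation, and the median was -3.54 within slide 1. When slide was a block, 11 lower genes passed. The value table gave a median of 3.37 and a difference of 3.37 for Defb14.

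The IL-23 and IL-17 axis, a cytokine circuit of psoriasis, could be measured only in part, with 8 of 15 genes on the array bright enough to test. Of these, 2 rose in the arrays filed under imiquimod, 2 fell and 4 did not pass; adjusted over the list alone, 2 rose and 3 fell. Ccl20, a chemokine ligand of Ccr6, rose by 3.11 (SE 0.59, adjusted p = 0.0172). A cytokine gene and a receptor gene fell, Il1b (-3.79, value-table value 3.74) and Il17rc (-0.68, value-table value 0.53). The median was -0.50 (camera adjusted p = 0.805) and -0.77 within slide 1, and 0 genes passed with slide as a block. Read from the value table, Ccl20 differed by -3.01, and the median was 0.45. Ccl20 did not pass with slide as a block (3.38, adjusted p = 0.102), with the replicate number as a block (3.11, adjusted p = 0.0568), without array 1 filed under imiquimod (adjusted p = 0.0644) or without array 1 filed under vehicle (adjusted p = 0.0667), and its difference was 3.12 and 2.97 in the latter 2.

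Of 19 measured genes of activated keratinocytes, 12 were lower in the arrays filed under imiquimod, 0 higher and 7 did not pass, with 12 lower adjusted over the list alone. Besides Krt6b, Serpinb3a, a protease inhibitor of squamous epithelium, differed by -4.42 (SE 0.27, adjusted p = 0.00143). The median was -1.63 (camera adjusted p = 1.63e-06), the call was lost, at adjusted p = 0.372 with an estimated correlation, and the median was -1.44 within slide 1. When slide was a block, 6 lower genes passed. The value-table median was 1.68, and Serpinb3a differed there by 4.42. Without both arrays of status evaluate the median was -2.74.

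Genes of the cornified envelope and terminal differentiation moved both ways: of 30 measured, 16 were lower in the arrays filed under imiquimod, 3 higher and 11 did not pass, and adjusted over the list alone 17 were lower and 5 higher. Sprr2b, a small proline-rich protein, differed by -5.67 (SE 0.35, adjusted p = 0.00143). Krt2, a keratin of the upper epidermis, was well above background on 0 arrays filed under vehicle and was at least 6.45-fold higher in the arrays filed under imiquimod (adjusted p = 0.00143). Besides Krt2, which was lower in the imiquimod columns of the value table, the genes that rose were Flg2 (5.56, value-table value -5.60) and Lce1c (0.98, value-table value -1.25). The Sprr2 genes are close copies, and their probes may bind more than 1 of them. The median was -0.64 (camera adjusted p = 0.00266), the call was lost, at adjusted p = 0.555 with an estimated correlation, and the median was -0.76 within slide 1. When slide was a block, 2 higher and 7 lower genes passed. The value table gave a median of 0.46 and a difference of 5.55 for Sprr2b. With normexp background correction the fitted difference of Krt2 was 1.59, against 4.61. The former is a smaller fold than the bound of Krt2, so that bound depends on the background correction.

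None of 28 measured cell cycle genes and none of 24 measured interferon-stimulated genes, Tlr7 included, passed in limma, whether over all genes, of which 6937 had an unadjusted p under 0.05, or adjusted over the list alone. Ccne1 and Ccne2, cyclins of the entry into DNA synthesis, differed by -0.88 (SE 0.34, adjusted p = 0.117) and 0.55 (SE 0.23, adjusted p = 0.138). Cxcl10, an interferon-induced chemokine, differed by -0.83 (SE 0.25, adjusted p = 0.0580), and Tlr7, the receptor for imiquimod, by -1.23 (SE 0.39, adjusted p = 0.0674). The medians were -0.39 for cell cycle (camera adjusted p = 0.0711) and 0.29 for interferon genes (camera adjusted p = 0.653), and -0.51 and 0.29 within slide 1, and no gene of either list passed with slide as a block. According to the value table, the medians were 0.39 and -0.28, and the 4 genes differed by 0.83, -0.44, 0.83 and 1.23. Array 3 filed under imiquimod stood apart from arrays 1 and 2: relative to each gene's mean over the 6 arrays, the cell cycle list stood at -1.10 in it against 0.14 and 0.24, and the interferon list at 1.31 against -0.14 and -0.70. Without it the cell cycle median was 0.014 (adjusted p = 0.888) and the interferon median -0.33 (adjusted p = 0.0441), and Cxcl10 and Tlr7 passed (adjusted p = 0.0345 and 0.0305). The cell cycle list passed without array 1 filed under imiquimod (-0.55, adjusted p = 0.00632), without array 2 (-0.68, adjusted p = 0.00539), with slide as a block (adjusted p = 0.0358), with the replicate number as a block (-0.39, adjusted p = 0.0331) and with no filter on dim probes (adjusted p = 0.0418). Cxcl10 also passed with normexp background correction (adjusted p = 0.0450), and the interferon median was -0.083 without both arrays of status evaluate. These list calls were made at the preset correlation; with an estimated correlation over all arrays (0.93 for cell cycle and 0.81 for interferon genes) the adjusted p was 0.799 and 0.901.

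Hair shaft and follicle genes had the list median farthest from 0 of the 23 lists: 15 of 21 measured genes were higher in the arrays filed under imiquimod, 0 lower and 6 did not pass, and 18 were higher adjusted over the list alone. Krt25 and Krt71 had the smallest p of the list. The median was 7.67, and also 7.67 with the 5 members that were dim throughout 1 group set at their bound. Camera gave an adjusted p of 4.06e-08, and the call was lost, at adjusted p = 0.439 with an estimated correlation. The median was 6.81 within slide 1, and 4 higher genes passed with slide as a block. Over genes well above background on all arrays it was 4.44. There the imiquimod response list, at -4.97, lay farther from 0, so the ranking did not hold. Relative to each gene's mean over the 6 arrays, the list stood at 4.68, 5.68 and 0.59 in arrays 1, 2 and 3 filed under imiquimod, and at -3.43, -3.20 and -3.06 in those filed under vehicle. The value-table median was -7.57.

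Of 18 measured sebaceous gland and sterol synthesis genes, 11 were higher in the arrays filed under imiquimod, 0 lower and 7 did not pass; adjusted over the list alone, 12 were higher and 1 lower. Elovl6, which lengthens fatty acids, rose by 3.83 (SE 0.31, adjusted p = 0.00206), and Soat1, which esterifies cholesterol, by 2.13 (SE 0.18, adjusted p = 0.00222). The median was 1.47 (camera adjusted p = 1.12e-05), the call was lost, at adjusted p = 0.372 with an estimated correlation, and the median was 1.53 within slide 1. The fit with slide as a block left 8 higher genes. By the value table the median was -1.54, and the 2 genes differed by -3.97 and -2.17. Over genes well above background on all arrays the median was 0.62.

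**Figure D3:**
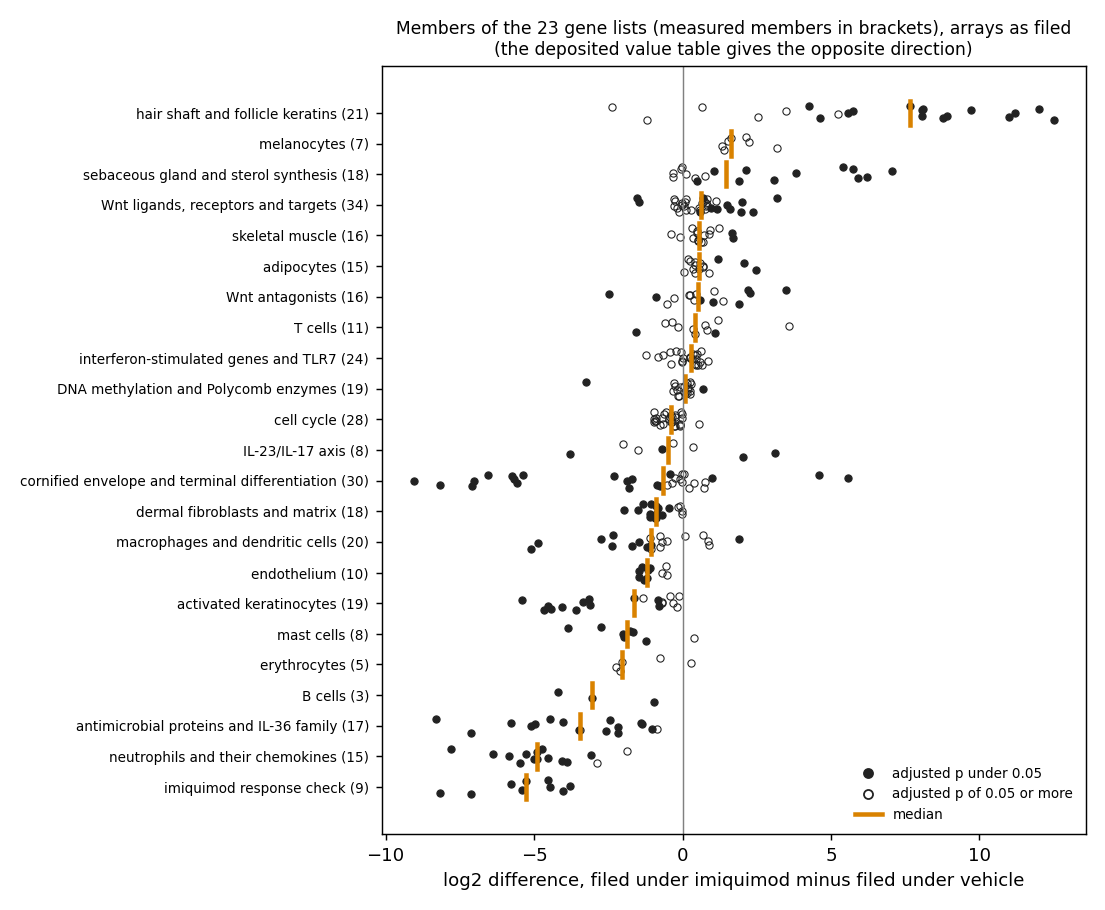
Log2 difference between the arrays filed under imiquimod and those filed under vehicle (horizontal axis) of each measured member of the 23 gene lists (vertical axis), with filled points for an adjusted p under 0.05, open points for the others and an orange bar for the median. The medians run from -5.26 for the imiquimod response list to 7.67 for the hair list, and the value table gives the opposite direction.

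Of 15 measured neutrophil genes and neutrophil chemokines, 13 were lower in the arrays filed under imiquimod, 0 higher and 2 did not pass; adjusted over the list alone, 14 were lower. Ngp, a neutrophil granule protein, was well above background on 0 arrays filed under imiquimod and was at least 16-fold lower there (adjusted p = 0.00127). The median was -4.90, or -4.52 with 3 dim members at their bound. Camera gave an adjusted p of 7.93e-09, the call was lost, at adjusted p = 0.372 with an estimated correlation, and the median was -5.53 within slide 1. When slide was a block, 9 lower genes passed. The value table gave a median of 4.87, and Ngp was higher in its imiquimod columns. With normexp background correction the median was -2.63 and the fitted difference of Ngp -2.52, against -5.84. A difference of -2.52 is a smaller fold than the bound of Ngp, so that bound depends on the background correction.

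Of 20 measured macrophage and dendritic cell genes, 9 were lower in the arrays filed under imiquimod, 1 higher and 10 did not pass (10 lower and 1 higher adjusted over the list alone). Cd14, a receptor for bacterial lipopolysaccharide, differed by -2.39 (SE 0.24, adjusted p = 0.00324), and the gene that rose was Cd207 (1.89, value-table value -1.89), a lectin of Langerhans cells. Of 8 mast cell genes, 7 were lower and 1 did not pass (7 lower adjusted over the list alone), and Fcer1a, a chain of the receptor for immunoglobulin E, differed by -3.87 (SE 0.27, adjusted p = 0.00167). Only 3 of 7 B cell genes on the array were bright enough to test. All 3 were lower, also adjusted over the list alone, and Cd79b, a chain of the B cell receptor complex, differed by -4.21 (SE 0.40, adjusted p = 0.00275). Its partner chain Cd79a was too dim to test and was well above background on 2 arrays filed under imiquimod and 0 filed under vehicle. Of 11 T cell genes, 1 was higher, 1 lower and 9 did not pass, with the same counts adjusted over the list alone: Cd5, a T cell surface receptor, differed by -1.55 (SE 0.15, adjusted p = 0.00279), and the kinase gene that rose was Lck (1.09, value-table value -0.99). The value-table differences were 2.32 for Cd14, 3.87 for Fcer1a, 4.19 for Cd79b and 1.53 for Cd5.

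The medians of these lists were -1.05 for macrophages and dendritic cells, -1.87 for mast cells (-1.73 with 1 dim member at its bound), -3.04 for B cells and 0.43 for T cells, in the arrays filed under imiquimod minus those filed under vehicle. The camera adjusted p was 0.00933, 0.00110, 0.0126 and 0.352. The first 3 calls were lost, at adjusted p = 0.555, 0.372 and 0.372 with an estimated correlation. Within slide 1 the medians were -0.97, -1.62, -3.06 and 1.24, and the T cell list passed at the preset correlation with slide as a block (adjusted p = 0.0230). With an estimated correlation (0.53) over all arrays its adjusted p was 0.799. With that block 1 lower gene passed in the macrophage and dendritic cell list, 1 lower gene passed in the mast cell list, 1 lower gene passed in the B cell list and 1 lower gene passed in the T cell list. Read from the value table, they were 0.90, 1.82, 2.95 and -0.41. The B cell median was -0.95 with no filter on dim probes and -0.81 with normexp background correction.

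Of 18 measured dermal fibroblast and matrix genes, 14 were lower in the arrays filed under imiquimod, 0 higher and 4 did not pass (14 lower adjusted over the list alone). Eln, which encodes elastin, differed by -1.06 (SE 0.097, adjusted p = 0.00260). Of 10 endothelial genes, 7 were lower, 0 higher and 3 did not pass (8 lower adjusted over the list alone), and Egfl7, a secreted protein of blood vessels, differed by -1.20 (SE 0.13, adjusted p = 0.00344). The medians were -0.89 and -1.19 (camera adjusted p = 2.96e-06 and 2.46e-05), and both calls were lost, at adjusted p = 0.439 with an estimated correlation. Within slide 1 they were -0.85 and -1.23. With slide as a block 4 lower genes passed in the fibroblast list and 2 lower genes passed in the endothelial list. The value table gave medians of 0.79 and 1.14, and differences of 1.07 for Eln and 1.13 for Egfl7.

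Of 15 measured adipocyte genes, 3 rose in the arrays filed under imiquimod and 12 did not pass (3 rose adjusted over the list alone); those that rose were Cidea (2.49, value-table value -2.62), Lep (2.07, value-table value -1.97) and Lgals12 (1.21, value-table value -1.17). For Cidea, a lipid droplet protein, the SE was 0.31 and the adjusted p 0.00546. Of 16 skeletal muscle genes, 2 rose and 14 did not pass (0 adjusted over the list alone): Myh1 (1.69, value-table value -1.90) and Mb (1.66, value-table value -1.78). For Mb, which encodes myoglobin, the SE was 0.37 and the adjusted p 0.0276. None of 7 melanocyte genes passed in limma in either adjustment, and Oca2, a melanosome protein well above background on 2 of 3 arrays filed under vehicle, differed by 3.17 (SE 1.33, adjusted p = 0.137). Of 5 erythrocyte genes 0 passed, 3 were lower adjusted over the list alone, and Alas2, an enzyme of heme synthesis, differed by -2.24 (SE 0.68, adjusted p = 0.0621). According to the value table, Oca2 differed by -3.03 and Alas2 by 2.20.

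The medians were 0.55 for adipocytes, 0.57 for muscle, 1.64 for melanocytes and -2.02 for erythrocytes, in the arrays filed under imiquimod minus those filed under vehicle. The camera adjusted p was 0.00146, 0.0236, 0.0396 and 0.152. The first 3 calls were lost, at adjusted p = 0.555, 0.671 and 0.60 with an estimated correlation. Within slide 1 the medians were 0.73, 0.64, 1.77 and -2.28, and by the value table -0.70, -0.74, -1.63 and 1.80. With slide as a block 2 higher genes passed in the adipocyte list and none in the other lists. Without array 3 filed under imiquimod the melanocyte median was 2.88 (adjusted p = 2.26e-06), the adipocyte median 0.20 (adjusted p = 0.0241) and the muscle median 0.26 (adjusted p = 0.129), and Oca2 passed (4.77, adjusted p = 0.00301). The melanocyte call was lost without array 1 or 2 filed under imiquimod (adjusted p = 0.101 and 0.186, the latter at 0.95), without array 1, 2 or 3 filed under vehicle (adjusted p = 0.0582, 0.0540 and 0.0550), with slide as a block (adjusted p = 0.0813) and over genes well above background on all arrays (adjusted p = 0.0679). The muscle call was lost without array 1 filed under imiquimod (adjusted p = 0.0688), without array 2 filed under vehicle (adjusted p = 0.102) and with slide as a block (adjusted p = 0.0702), and the median was 0.98 without array 2 filed under imiquimod and 0.85 without array 3 filed under vehicle. Mb did not pass with slide as a block (adjusted p = 0.195), without array 1 filed under imiquimod (adjusted p = 0.0742) or without array 1, 2 or 3 filed under vehicle (adjusted p = 0.0753, 0.0888 and 0.0720), while its difference was 1.44 to 1.78 in these. The erythrocyte list and Alas2 passed without array 3 filed under vehicle (-2.55, adjusted p = 0.0283, and -2.86, adjusted p = 0.0423). Over all arrays the adjusted p of the erythrocyte list was 0.60 with an estimated correlation.

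**Figure D4:**
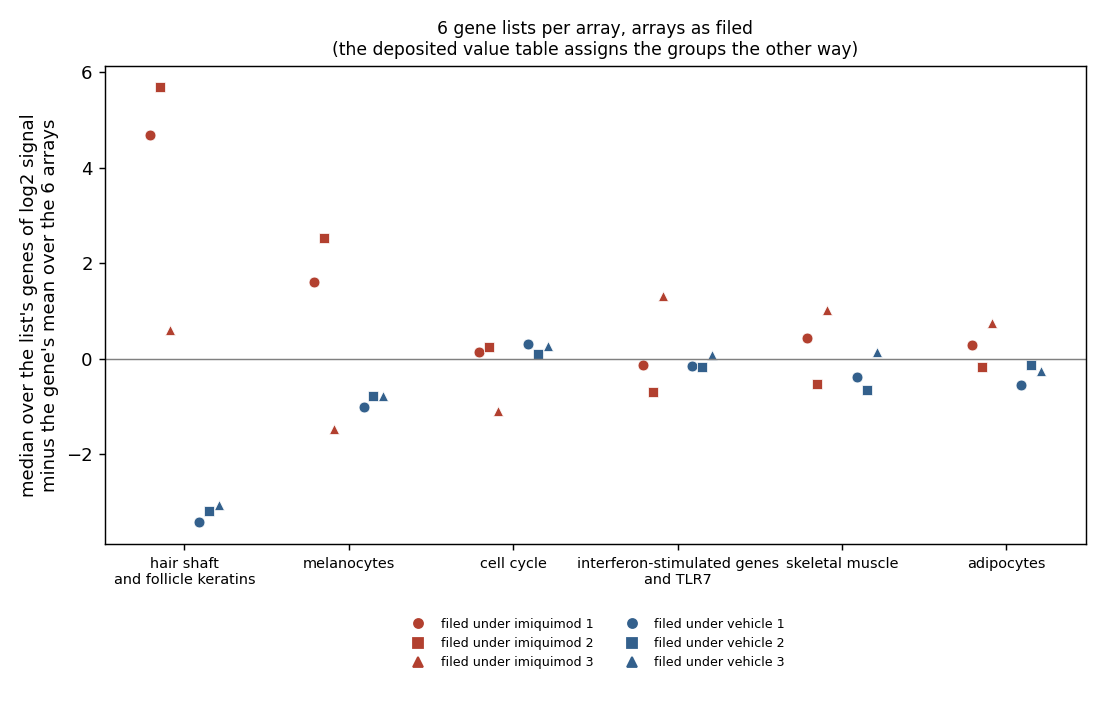
Median over a list's genes of the log2 signal minus the gene's mean over the 6 arrays (vertical axis) for 6 gene lists (horizontal axis), with 1 point per array, coloured by the group its scanner file was filed under. Array 3 filed under imiquimod lies at 0.59 in the hair list, -1.47 in the melanocyte list and -1.10 in the cell cycle list, below arrays 1 and 2 in each, and at 1.31 in the interferon list, above both; the value table assigns the groups the other way.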

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

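The alternative that left out both arrays of status evaluate was chosen after seeing the data. It leaves 1 array filed under imiquimod, so the arrays filed under vehicle give all the spread, and it gave 1344 higher, 1617 lower and 2136 at least 2-fold different. Under quantile normalization, normexp, either filter, the mean of probes and the variance trend, 1310 to 1915 genes were higher, 1564 to 2577 lower and 1479 to 2160 at least 2-fold different. Slide as a block gave 518 higher, 541 lower and 994 at least 2-fold different, with 991 of the 4196 genes still called. Slide 1 alone gave 1, 7 and 8, and 0 named genes against 34; it has 4 arrays, 1 of them filed under vehicle. The replicate block gave 1043 higher and 1164 lower; the numbers did not pair the samples. Leaving out each array in turn gave 745 to 2215 higher, 944 to 2514 lower, 1307 to 2408 at least 2-fold different, 14 to 17 lists, 30 to 37 named genes and a response list median of -5.61 to -4.61. With no fold threshold 4196 genes changed, and 772 did by a log2 value of at least 2. With an estimated correlation camera called 0 lists, the response list (-5.26) at adjusted p = 0.372. Signal over background left Il17a, Il17f, Il22 and Il23a untested. Without array 2 filed under imiquimod the DNA methylation median was -0.036; without array 3 the cell cycle median was 0.014 and the interferon median -0.33, and without both the latter was -0.083. Over all arrays left out in turn the DNA methylation median lay at -0.036 to 0.15, that of cell cycle at -0.68 to 0.014 and that of interferon genes at -0.33 to 0.73. The cause was not tested for these.

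Each value-table column matched an array filed under the other group, and its values, read by sample title, were reversed. The response list median was 5.21. The other medians were 0.45 for the IL-23 and IL-17 axis, 3.37 for antimicrobial genes, 1.68 for activated keratinocytes, 0.46 for the cornified envelope, -0.52 for Wnt antagonists, -0.62 for Wnt ligands and targets, -7.57 for hair, -1.54 for sebaceous gland, 4.87 for neutrophils, 0.90 for macrophages, -0.41 for T cells, 2.95 for B cells, 1.82 for mast cells, 1.14 for endothelium, 0.79 for fibroblasts, -0.70 for adipocytes, -0.74 for muscle, -1.63 for melanocytes, 1.80 for erythrocytes, 0.39 for cell cycle, -0.28 for interferon genes and -0.060 for DNA methylation. The named genes reported differed by -1.95 for Sfrp1, 2.44 for Sfrp2, -0.25 for Frzb, -2.20 for Sfrp4, -0.11 for Sfrp5, 8.87 for Sprr2f, 8.20 for Saa3, 7.96 for Sprr2d, -12.56 for Krt25, -12.08 for Krtap22-2, -11.97 for Krt71, 5.21 for Krt6b, 4.43 for Lcn2, 3.97 for Il36a, -3.01 for Ccl20, 3.37 for Defb14, 4.42 for Serpinb3a, -4.42 for Krt2, 5.55 for Sprr2b, 0.83 for Ccne1, -0.44 for Ccne2, 0.83 for Cxcl10, 1.23 for Tlr7, -3.45 for Notum, -2.02 for Wnt3, 1.52 for Wnt4, 3.27 for Dnmt3l, -0.71 for Tet3, -3.97 for Elovl6, -2.17 for Soat1, 5.69 for Ngp, 2.32 for Cd14, 1.53 for Cd5, 4.19 for Cd79b, 3.87 for Fcer1a, 1.13 for Egfl7, 1.07 for Eln, -2.62 for Cidea, -1.78 for Mb, -3.03 for Oca2 and 2.20 for Alas2. Those of Krt25, Krtap22-2, Krt2 and Ngp are fitted against signals not well above background, and those of Sprr2f, Notum, Krt71, Oca2 and Sfrp5 partly so, so their size is not established.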

Other observations

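The families in this paragraph and the next, symbols with a shared stem and at least 8 tested members, the root sheath list and the test that left out array 1 filed under vehicle were chosen after the data were seen; 256 families were tested in each direction by Fisher's exact test, one-sided, against 11897 genes. Matrix metalloproteinases, which cleave extracellular matrix, were lower in the arrays filed under imiquimod in 10 of 16 members (adjusted p = 4.42e-04), and kallikrein-related peptidases in 7 of 13 (adjusted p = 0.0253). Klra receptor genes were lower in 9 of 10 (adjusted p = 1.01e-05) and beta-protocadherins in 12 of 16 (adjusted p = 5.33e-06). Keratin-associated proteins of hair were higher in 28 of 37 (adjusted p = 7.55e-18). Genes with the stem Pex, grouped by symbol and not by function, were higher in 7 of 17 (adjusted p = 0.0334). Claudins of tight junctions were higher in 7 of 17 (adjusted p = 0.0334), with 1 lower. The Fisher tests of families count genes measured on the same arrays, which are not independent replicates. Other families that passed are not reported here. Probes of the Klra, Pcdhb and Krtap families, which hold close copies, were not tested for binding to more than 1 member. The members counted in these families may therefore not be separate measurements. With slide as a block 7 metalloproteinases, 3 kallikreins, 1 Klra gene and 2 beta-protocadherins were lower, and 2 keratin-associated proteins, 3 claudins and 1 Pex gene higher. In the imiquimod columns of the value table, 10 metalloproteinases, 6 kallikreins, 9 Klra genes and 13 beta-protocadherins were higher, and 27 keratin-associated proteins, 7 claudins and 6 Pex genes lower.

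Calls among ribosomal protein genes depended on the processing. Of 48 Rpl genes, 25 were lower in the arrays filed under imiquimod (median -0.36, adjusted p = 4.17e-08), against 3 with quantile normalization (median -0.096), 27 with normexp background correction and 0 with slide as a block (median -0.39). In the value table, 3 were higher in the imiquimod columns (median 0.088).

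The imiquimod response list had a median of -5.26 in the arrays as filed. If the labels of the groups had been exchanged, the median would lie under -1 with every array on the side opposite to its filing, and in 9 of 9 genes all 6 arrays did. The words in the 6 file names and the 6 value-table columns go with that exchange. A candidate explanation is that the scanner files were attached to the samples of the other group, in which case every direction given for the arrays as filed turns, that of Sfrp4 included. A fall of these genes under imiquimod would require the words in all 6 file names and all 6 value-table columns to be wrong. Those records argue against a fall, but no record in the files settles which attachment is right.

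Between the groups 4196 genes were called. The real split was 1 of 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The highest of the other splits called 0. Each of those splits mixes both groups on both sides, so the group difference adds to the spread and the 0 says little about chance. Within slide 1 the median ratio of the differences of the called genes to those over all arrays was 1.05, but this does not decide on a difference between slides, because calling a gene requires the arrays of a group to agree. Array 1 filed under vehicle was therefore left out, and 1782 genes were called between the 3 arrays of slide 1 filed under imiquimod and the 2 arrays of slide 2. A difference between slides as the whole cause would put the left-out array, which is on slide 1, near the arrays filed under imiquimod. On a scale from 0 at their mean to 1 at the mean of the slide 2 arrays, its median place was 1.04 (5th to 95th percentile 0.615 to 1.53), which argues against that cause but rests on 1 array. Over all 17778 genes, the arrays filed under vehicle differed between slides by a median absolute log2 value of 0.154, and the groups by 0.344. A smaller share of the slide in the differences stays open, as does the treatment, in either direction.

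The hair list had a median of 7.67. A smaller share of follicle tissue in the samples filed under vehicle, as the whole cause, would move genes specific to the follicle by a similar amount. Outer root sheath and bulge genes had a median of 0.87 (range 0.52 to 3.01, 10 genes). The exact two-sided rank sum test against the 21 hair genes gave p = 7.59e-04, across genes, which are not independent replicates. Whether these 10 genes are expressed in the follicle alone was not tested. The comparison therefore does not decide on that share as the whole cause. Of the 10 root sheath and bulge genes, 6 were higher, 0 lower and 4 did not pass (7 higher adjusted over the list alone). This goes in the direction of a smaller share. The sebaceous gland list went the same way, with 11 of 18 genes higher, 0 lower and a median of 1.47. Such a share, as the whole or a part of the difference, stays open. By the value table the root sheath median was -0.96. A difference between slides, as the whole cause, would leave the hair list near 0 within slide 1, where its median was 6.81. That median rests on 1 array filed under vehicle. The treatment and the stage of the hair cycle, which the labels do not give, stay open and were not tested.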
